A study of Mus musculus with 4 samples.

How the data were processed

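Gene expression was measured in mouse CD4+ T cells on Affymetrix oligonucleotide arrays, which read each transcript with 1 or more probe sets. Per the labels' protocols, naive CD4+ T cells were activated with soluble anti-CD3 antibody at 0.5 ug/ml, IL-2 at 20 u/ml and splenocytes that had been depleted of T cells and treated with mitomycin C, and were then infected with a retrovirus. The retrovirus carried no insert (empty vector), AML1 (the transcription factor encoded by Runx1), wild-type Foxp3 (the lineage factor of regulatory T cells) or a mutant Foxp3 that does not bind AML1. Cells positive for green fluorescent protein, the marker of infection, were sorted 60 hours after transfection and total RNA was isolated on columns and labelled with biotin by a one-cycle protocol. There were 4 arrays, 1 per group, so no test between groups was possible and no p-value or standard error is given; the number of arrays limits the precision of every value.

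The values are the probe set signal intensities deposited by the authors, with 1 column per array. GCOS, the array maker's software, was used per the submitters' processing notes; its version, its settings and any global scaling are not given in the sources used here. The deposited intensities are linear: none is negative and the medians of the 4 columns were 14.8 for the empty vector, 14.7 for AML1, 14.7 for wild-type Foxp3 and 15 for the Foxp3 mutant. The columns are levels per array and not ratios, so they carry no direction, and no centring of genes across arrays was seen; whether the authors scaled the arrays to a common target stays unknown. No detection calls and no scanner images were used here.

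Each column held 45101 probe sets, of which 64 control probe sets were set aside and 45037 analysed. Every array was scaled to the same mean after trimming 2% of the values at each end. The trimmed means as deposited were 105.71 for the empty vector, 99.583 for AML1, 90.002 for wild-type Foxp3 and 92.78 for the mutant, which gave scaling factors of 0.918, 0.974, 1.08 and 1.05. Scaled signals were then raised to a floor at the 40th percentile of all 4 arrays pooled, a signal of 8.95, and converted to log2. A gene entered a comparison if the brighter of its 2 arrays reached the pooled 50th percentile, a signal of 14.91. A gene was called higher or lower if the arrays differed by 2-fold or more, which is a rule of size and not a test. Where the dimmer array lay at or below the floor, the fold is a lower bound and is written as at least that fold. All signals in the text are scaled signals in arbitrary units.

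Gene names came from GEO's platform annotation, which can be old, and were looked up by Entrez number in the RefSeq gene table of assembly GRCm38.p6, which was used for names only: 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none, 34741 of the first kind matched the table, and 0 symbols needed an update. Probe sets with several symbols or none were not named. A gene was represented by its probe set with the highest mean signal over the 4 arrays, which gave 18193 genes, 9010 of them with more than 1 probe set; where another probe set of a named gene above the brightness minimum had the opposite sign, or where none of the others reached 2-fold for a called gene, this is said. The files give no coordinates and no genome build, so no positions are given, and the positions of the probes relative to the inserts of the retroviruses are not given in the sources used here.

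The comparisons were AML1, wild-type Foxp3 and the Foxp3 mutant each with the empty vector, and wild-type Foxp3 with the mutant. The genes named for a comparison were the transduced genes Foxp3 and Runx1 with each probe set, the 10 named genes with the largest differences in each direction, and up to 4 members with the largest absolute log2 ratio from each of 24 gene lists. The lists covered Treg-associated genes, genes known as low in Treg cells, T cell cytokines, helper lineage transcription factors, activation and checkpoint genes, naive and quiescence genes, chemokines and their receptors, cytotoxic granule and killing genes, cytokine receptors with STAT and SOCS genes, T cell receptor signalling, the RUNX family and partners, cell cycle, interferon-stimulated genes, glycolysis, cholesterol synthesis, apoptosis, heat shock with endoplasmic reticulum stress, class II antigen presentation, and markers of B cells, myeloid cells, dendritic cells, CD8 T and NK cells, erythroid cells, and fibroblasts and stroma. Of 353 list genes, 320 were on the arrays under that name, and some genes stand in several lists. The lists, the rule for named genes, the floor, the brightness minimum and the alternatives were chosen before the data were examined. For each list the median log2 ratio of the members above the brightness minimum was set among those of 10000 random lists of the same size, matched on mean signal in 10 bins, and its percentile is given as a description of these arrays. Intervals of list medians are exact 95% order-statistic intervals over the members and do not include variation between arrays. For short lists the interval spans all members, and for the shortest its coverage is below 95%. Lists with fewer than 3 such members got counts only.

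Because all 3 vector comparisons share the empty vector array, its chance values enter each of them. Overlaps and correlations between them are therefore given beside 100 simulations of 4 arrays without any effect, with noise taken per brightness bin from the difference between the mutant and the empty vector, which also contains any real difference and so overstates the noise. Pairs of comparisons that share no array were used as the main measure of relation, although AML1 then serves as a reference and its own differences enter. Shares have exact Clopper-Pearson 95% intervals over genes, and correlations have bootstrap intervals over 1000 resamplings of genes; genes are not independent replicates. The calling rule was tested on simulated data with 100 changed dim and 100 changed bright genes at 4-fold and at 8-fold among 18193 genes. For the comparison of wild-type Foxp3 with the empty vector it recovered 96% of dim and 100% of bright 4-fold changes, and it called 6.62% of unchanged dim genes and 0% of unchanged bright genes. For the mutant it recovered 90% of dim and 100% of bright 4-fold changes and called 6.68% of unchanged dim and 0.0628% of unchanged bright genes. The figures for AML1 were 97%, 100%, 6.51% and 0.0314% in the same order, and those for wild-type Foxp3 against the mutant were 92%, 100%, 5.96% and 0.0157%. Dim and bright were set here by the mean over the 4 arrays, whereas the counts below use the brighter of the 2 arrays compared. The noise also holds the mutant's own difference from the empty vector. These rates therefore do not give the share of false calls in the counts below. Of 200 unchanged lists of 20 genes simulated for wild-type Foxp3 against the empty vector, 5.5% fell in the lowest or highest 2.5% of random lists. This share checks the calculation only, because these lists were themselves random genes with independent noise. It does not show how often lists of genes that vary together would fall there.

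The alternatives were quantile normalization, centring on the median of the brighter probe sets, a floor at the 20th percentile, no floor with a pseudocount of 2.48, a brightness minimum at the 75th percentile (a signal of 88.57), no brightness minimum, the median of a gene's probe sets, and a requirement that all its probe sets share 1 sign. The split of each count into dim and bright genes at the 75th percentile was chosen after the data were seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.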

Results

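The data are 4 Affymetrix arrays of mouse CD4+ T cells that were activated, infected with a retrovirus and sorted for infection. The retrovirus was empty or carried AML1, wild-type Foxp3 or a mutated Foxp3 that cannot bind AML1, with 1 array for each. AML1, encoded by Runx1, is a transcription factor of the Runt family that acts at cytokine genes in T cells. Foxp3 is the transcription factor that defines regulatory T (Treg) cells. The comparisons ask how gene expression differs with each factor and which part of the wild-type Foxp3 pattern is absent with the mutant. The arrays do not show whether wild-type and mutant Foxp3 were made in equal amounts. A difference between those arrays therefore cannot be assigned to the binding of AML1. There were no replicates, so the values below compare 4 arrays by size of difference, and the number of arrays limits their precision. Over 10241 genes the median absolute log2 difference was 0.18 between the mutant and the empty vector, 0.21 between wild-type Foxp3 and the mutant, 0.26 between wild-type Foxp3 and the empty vector and 0.29 between AML1 and the empty vector.

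The transduced genes were examined first. The single Foxp3 probe set gave signals of 15.5 on the empty vector array, 11.7 on the AML1-labelled array, 13.9 on the array labelled wild-type Foxp3 and 10.7 on the array labelled mutant, so neither Foxp3 array showed a raised Foxp3 signal. Runx1 had 6 probe sets, and 6 of 6 were lowest on the AML1-labelled array. The smallest difference from the empty vector was 1.63-fold and the largest measured above the floor was 7.39-fold, while 2 of the probe sets read 0.5 and 5.8 there, below the floor, so that their folds are lower bounds. The brightest Runx1 probe set read 98.4 on the empty vector array, 28.6 on the AML1-labelled array, 84.6 on the wild-type array and 113.4 on the mutant array. Where these probe sets lie relative to the inserts is not given in the sources used here, and a probe set outside an insert checks nothing about the vector. These genes therefore bore out none of the labels, and the Runx1 signal ran against the AML1 label, so every direction below rests on the labels alone. Arrays are called by their labels throughout, and "with AML1" stands for the array labelled AML1.

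On the array labelled AML1, several genes of cytotoxic granules gave higher signals, and several Treg-associated genes and chemokine receptors gave lower signals than on the empty vector array, while T cell cytokines went both ways. Granzyme C (Gzmc), a granule protease, was 14.3-fold higher, at 2380 against 166.2, and Nkg7, a granule membrane protein of killer cells, was 7.46-fold higher, at 1956 against 262.2. Cxcr3, the receptor for interferon-induced chemokines, was 14.4-fold lower, at 14.3 against 205.9. Among the cytokine genes, Il21 and Il4 were 10.5-fold and 7.38-fold lower and Ifng was 2.38-fold higher. In total 531 genes were higher and 446 lower by 2-fold or more among 10672, and among the 6876 bright genes 172 were higher and 199 lower.

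The other genes with the largest higher signals on the AML1-labelled array were Gstm5, a glutathione transferase, at 14.6-fold, Cdh1 (E-cadherin) at 98.6 against a signal below the floor, the aquaporin Aqp9 at 9.69-fold, the stem cell factor receptor Kit at 9.11-fold, Echdc2 at 8.47-fold, the NK cell receptor Cd244a at 8.43-fold, Bst1 at 7.99-fold and Cables1 at least 7.35-fold. Second probe sets of Aqp9, Kit, Cd244a and Bst1 were higher too. The largest lower signals were those of the tetraspanin Tspan32 at 28.0-fold, the gap junction gene Gja1 at 17.7-fold, and the unconventional myosin Myo6 at 14.6-fold, from 3061 to 209.3. Next came Rundc3a at least 9.86-fold, the steroid synthesis enzyme Cyp11a1 at 8.32-fold, Lyl1 at least 8.15-fold, Inf2 at 7.94-fold and Samd10 at least 7.64-fold lower. For Gja1 the other 5 probe sets and for Myo6 the other 2 were lower as well.

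Of 13 cytotoxic genes above the brightness minimum, 5 were higher, 1 lower and 7 neither, with a median log2 ratio of 0.95 (interval -0.30 to 1.52) at percentile 100 of the random lists. Gzma was 2.87-fold higher and Gzmd at least 2.58-fold higher. The lower gene, chosen after its values were seen, was Prf1 (perforin) at 2.55-fold, 41.2 against 105.3, with a second probe set at a log2 ratio of -0.16. Of 26 Treg-associated genes, 0 were higher, 10 lower and 16 neither, with a median of -0.77 (-1.11 to -0.17) at percentile 0. Izumo1r, the folate receptor 4 of Treg cells, was 5.65-fold lower, Il10 5.12-fold lower, the cytokine subunit Ebi3 3.85-fold lower and Socs2 3.03-fold lower, the last with log2 ratios below 0 in its other 4 probe sets. Genes known as low in Treg cells also lay low, with 1 higher, 3 lower and 8 neither of 12 and a median of -0.50 at percentile 0.03. In this list Igfbp4 was 2.92-fold lower, while Ifng, the T helper 1 cytokine, was higher at a dim 43.9 against 18.4.

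Chemokines and their receptors had 1 higher, 8 lower and 5 neither of 14, with a median of -1.17 at percentile 0, which became -2.11 with the brightness minimum at the 75th percentile and -0.73 without one, both at percentile 0. Cxcr4 was 5.95-fold and Ccl5 5.20-fold lower, and Cxcr6 was 4.71-fold higher. T cell cytokines split into 3 higher, 4 lower and 5 neither of 12 (median -0.24, percentile 4.19, and -1.13 at percentile 0 with the minimum at the 75th percentile), with Il17a 4.03-fold lower. Helper lineage transcription factors had 1 higher, 2 lower and 10 neither of 13 (median -0.54, percentile 0, and -0.33 with the median of a gene's probe sets). Eomes, a factor of killer lineages, was 5.34-fold higher, Runx3 was 4.61-fold lower, at 240.1 against 1107, and Maf was 2.46-fold lower in the probe set used, with the 5 others lower as well. Activation and checkpoint genes had 3 higher, 1 lower and 14 neither of 18 (median 0.16, percentile 95.3). Havcr2, the checkpoint receptor TIM-3, was 4.83-fold, Pdcd1 2.26-fold and Egr3 2.14-fold higher, and Egr2 was 2.22-fold lower. Naive and quiescence genes had 0 higher, 3 lower and 9 neither of 12 (median -0.51, percentile 0.01), with Il6ra 5.48-fold, Klf2 2.42-fold and S1pr1 2.41-fold lower.

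Cytokine receptors with STAT and SOCS genes had 0 higher, 3 lower and 22 neither of 25 (median -0.37, percentile 0), with Socs3 2.47-fold and Ifngr2 2.41-fold lower. The 24 cell cycle genes had none past 2-fold and a median of 0.28 (0.11 to 0.44) at percentile 100, with Mcm2, a subunit of the replicative helicase, at 1.68-fold higher. The 13 cholesterol synthesis genes likewise had none past 2-fold and a median of 0.36 at percentile 99.9, with Sc5d at 1.60-fold higher. Apoptosis genes had 0 higher, 1 lower and 11 neither of 12 (median -0.21, percentile 2.47, and percentile 2.60 under quantile normalization), with Birc3 2.14-fold lower. Further lists outside the extreme 2.5% at either end were T cell receptor signalling (1 higher and 14 neither of 15, median -0.15), RUNX family and partners (2 lower and 6 neither of 8, median 0.03, mean -0.37), interferon-stimulated genes (1 higher, 2 lower and 14 neither of 17, median -0.01), glycolysis (0 past 2-fold of 13, median 0.07) and heat shock with endoplasmic reticulum stress (1 lower and 13 neither of 14, median 0.14, but 0.29 at percentile 99.025 with the median of a gene's probe sets). In the last of these Xbp1, a secretory cell factor, was 2.16-fold lower. In T cell receptor signalling the higher gene was Trat1 at 3.33-fold, and its second probe set stayed under 2-fold, at a log2 ratio of 0.48. The same held for the second probe sets of Il6ra at -0.76, Egr3 at 0.58 and Birc3 at -0.98.

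Markers of other cells moved with these groups. Of 8 B cell markers, 0 were higher, 6 lower and 2 neither, with a median of -1.30 at percentile 0: Blnk was 3.59-fold, Fcer2a at least 3.27-fold and Ighm 3.02-fold lower, Ighm at 386.4 against 1166. Of 5 class II antigen presentation genes, 2 were lower and 3 neither (median -0.68, percentile 0.18), with H2-Aa 2.84-fold and Cd74 2.52-fold lower and H2-Ab1 at a log2 ratio of 0.35. CD8 T and NK cell markers had 0 past 2-fold of 4 (median -0.69, percentile 1.31, but -0.29 without a brightness minimum and -0.17 at percentile 16.0 with the median of a gene's probe sets); Cd8a lay at -0.79 in the probe set used while its 3 others lay above 0. Myeloid markers had 1 higher, 1 lower and 5 neither of 7 (median 0.14, percentile 48.8), and dendritic cell markers 1 lower and 4 neither of 5 (median -0.78, percentile 3.66). No erythroid or stromal marker reached the brightness minimum in this comparison. Of the 22 lists with a percentile, 3 lay in the highest 2.5% of random lists and 10 in the lowest 2.5%, where 1.1 in all would be expected of lists of unrelated genes. Members of a list can vary together, so the number expected by chance for these lists is not known. Where a called gene had a second probe set above the brightness minimum, it went the same way in 318 of 341 genes (93.3%, exact interval 90.1 to 95.7).

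**Figure D1:**
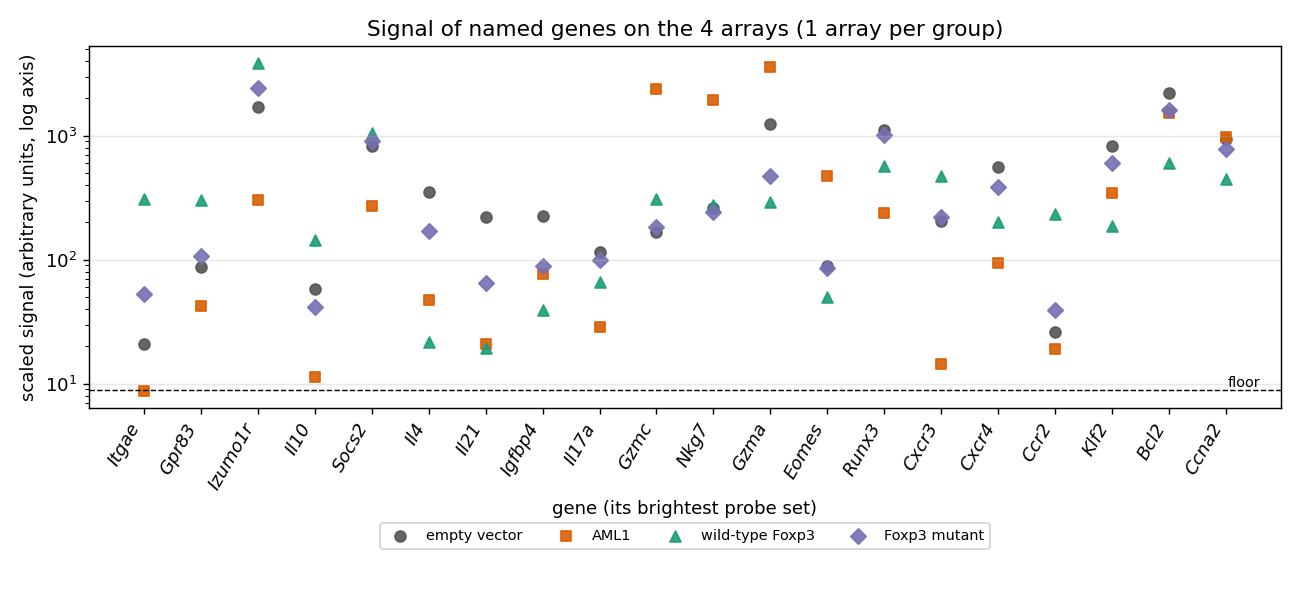
Scaled signal (log axis, arbitrary units) of 20 genes on the 4 arrays, with 1 point per array, each gene read by its brightest probe set; the dashed line is the floor. Itgae lies at 310.5 with wild-type Foxp3 and 21.0 with the empty vector, Gzmc at 2380 with AML1 and 166.2 with the empty vector, and Il4 at 350.9 with the empty vector and 21.8 with wild-type Foxp3.

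On the array labelled wild-type Foxp3, several Treg-associated genes gave higher signals, while the cytokines Il4 and Il21 and the survival gene Bcl2 gave lower signals than with the empty vector, and cell cycle genes lay lower, nearly all by less than 2-fold. Itgae, the integrin chain CD103 of tissue Treg cells, was 14.8-fold higher, at 310.5 against 21.0. The chemokine receptor Ccr2 was 8.95-fold higher. Il4, the T helper 2 cytokine, was 16.1-fold lower, at 21.8 against 350.9, and Il21 was 11.3-fold lower. In total 640 genes were higher and 279 lower among 10984, a split that quantile normalization moved to 496 and 343. Among the 6784 bright genes 132 were higher and 112 lower.

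The largest higher signals with wild-type Foxp3 also included the aminopeptidase Enpep at least 21.3-fold, the adhesion gene Mpzl2 at least 14.4-fold, the plasminogen activator Plat at least 10.1-fold and the adhesion molecule Epcam at 9.12-fold. They were followed by Rgs2, a regulator of G protein signalling, at 7.60-fold, Postn at 7.09-fold, Abcc5 at 6.80-fold and the metallothionein Mt2 at 6.74-fold. The other 4 probe sets of Abcc5 lay between -0.40 and 0.58 and did not bear out its value. Those of Mpzl2, Epcam, Ccr2 and Rgs2 were all higher. The largest lower signals also included the hypoxia-inducible factor Epas1 at 12.3-fold and Ctla2a, an inhibitor of cysteine proteases, at 11.3-fold. They continued with Slc2a6 at least 9.29-fold, Ctla2b at 7.09-fold, Cysltr1 at least 6.76-fold, the potassium channel Kcnk5 at 6.48-fold, Myo6 at 5.96-fold and Mgll at 5.83-fold lower.

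Of 26 Treg-associated genes, 6 were higher, 1 lower and 19 neither, with a median of 0.37 (0.23 to 0.62) at percentile 100. Gpr83, a receptor of Treg cells, was 3.45-fold higher in the probe set used and higher in the second, Il10 was 2.46-fold and the actin capping gene Capg 2.35-fold higher, the last with a second probe set at -0.06. Of 12 genes known as low in Treg cells, 0 were higher, 5 lower and 7 neither (median -0.57, -2.51 to 0.09, percentile 0); Igfbp4 was 5.70-fold lower with the other 5 probe sets lower too, and the phosphodiesterase Pde3b was 2.21-fold lower. T cell cytokines had 1 higher, 3 lower and 8 neither of 12 (median -0.49, percentile 0.08, but 0 at percentile 32.3 without a brightness minimum), Il24 being at least 4.80-fold lower. Activation and checkpoint genes had 1 higher and 17 neither of 18 (median 0.32, percentile 100), with Egr1 2.15-fold higher and Cd69 at 1.84-fold.

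The 24 cell cycle genes had 0 higher, 1 lower and 23 neither, with a median of -0.68 (-0.80 to -0.61) at percentile 0. Ccna2 (cyclin A2) was 2.11-fold lower, and Birc5 and the helicase subunit Mcm3 lay at 1.92-fold and 1.89-fold lower; of the other 4 probe sets of Mcm3, 3 were lower too and 1 lay at 0.12. Apoptosis genes had 1 higher, 2 lower and 9 neither of 12 (median -0.04, percentile 26.2). Bcl2, which protects from apoptosis, was 3.68-fold lower, at 603.1 against 2219, with the other 4 probe sets between -1.93 and -1.65, while its relative Bcl2l1 was 2.12-fold higher and Cdkn1a 2.02-fold lower. Cytotoxic genes had 0 higher, 3 lower and 8 neither of 11 (median -0.04, percentile 24.6), with Gzma 4.27-fold, Fasl 3.67-fold and Klrd1 2.07-fold lower. Chemokines and receptors had 3 higher, 2 lower and 8 neither of 13 (median 0.35, percentile 94.8, but 97.8 with the median of a gene's probe sets), with Cxcr3 2.31-fold higher, Ccl3 at least 2.55-fold higher and Cxcr4 2.77-fold lower. Naive and quiescence genes had 1 lower and 11 neither of 12 (median 0.20, mean -0.07, percentile 97.3, but 97.6 with median centring and 97.7 without a brightness minimum), and the lower gene was the trafficking factor Klf2 at 4.47-fold. Cytokine receptors with STAT and SOCS genes had 2 lower and 23 neither of 25 (median 0.13, mean -0.05, percentile 94.6), the lower ones being Il18rap at 2.33-fold and Il18r1 at 2.17-fold.

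Helper lineage transcription factors had 0 past 2-fold of 13 (median -0.08, percentile 18.1), with Runx3 at 1.95-fold lower. The RUNX family had 0 of 8 (median -0.24, percentile 2.93, but 2.23 without a brightness minimum). T cell receptor signalling had 1 higher and 14 neither of 15 (median -0.02, mean 0.07, percentile 30.5); the higher one was Trat1, whose second probe set lay at 0.08. Interferon-stimulated genes had 2 higher and 16 neither of 18 (median 0.06, percentile 52.9), with Isg20 2.09-fold higher. Glycolysis had 0 past 2-fold of 13 (median 0.13, percentile 90.2) and cholesterol synthesis 0 of 13 (median -0.00, percentile 47.6). Heat shock with endoplasmic reticulum stress had 1 higher and 13 neither of 14 (median -0.01, mean 0.01, percentile 33.2), Hspa1b being 2.03-fold higher at a dim 29.4. Second probe sets stayed under 2-fold for Cysltr1 at a log2 ratio of -0.92, Ccna2 at -0.90, Cdkn1a at -0.65 and Il18rap at -0.66.

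Among markers of other cells, myeloid markers had 4 higher and 4 neither of 8, with a median of 0.86 at percentile 98.9, which fell to 0.18 at percentile 92.8 without a brightness minimum. These were dim signals: Itgam was 3.45-fold higher at 52.5, Tyrobp 2.34-fold at 27.7, Csf1r 2.30-fold at 36.3 and Cd68 2.16-fold at 63.7. B cell markers had 1 higher, 1 lower and 6 neither of 8 (median 0.03, percentile 27.6), dendritic cell markers 2 lower and 2 neither of 4 (median -0.31, percentile 6.35), class II genes 0 of 6 (median -0.14, percentile 14.1) and CD8 T and NK cell markers 1 lower and 3 neither of 4 (median 0.17, mean -0.27, percentile 62.6). The lower NK marker was Klrk1 at 3.19-fold. Of stromal markers 1 was higher and 1 neither of 2, Sparc being at least 2.21-fold higher, and no erythroid marker reached the minimum. Of 22 lists, 3 lay in the highest 2.5% of random lists and 3 in the lowest 2.5%. Second probe sets went the same way as the call in 220 of 264 genes (83.3%, 78.3 to 87.6), and in 119 of 130 bright genes (91.5%, 85.4 to 95.7).

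On the array labelled Foxp3 mutant, few bright genes differed from the empty vector, and the Treg-associated list did not stand apart. The adhesion gene Mpzl2 was at least 12.5-fold higher, at 111.4 against 8.0, with its other 2 probe sets higher too. Il21 was 3.39-fold, Gzma 2.66-fold, Igfbp4 2.51-fold and Il4 2.06-fold lower, the last at 170.0 against 350.9. Counts were 360 higher and 137 lower among 10873, and quantile normalization moved this split to 284 and 187. The count of higher genes was 547 with the floor at the 20th percentile and 223 with the median of a gene's probe sets. Among the 6649 bright genes 21 were higher and 14 lower.

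Apart from Mpzl2 and Il21, the genes with the largest differences on the mutant-labelled array were dim. Utf1 was at least 6.41-fold, Lce3c at least 5.69-fold, Cysrt1 at least 5.42-fold, the neurotrophin receptor Ntrk2 5.42-fold, Dpf3 at least 4.91-fold, Obsl1 at least 4.73-fold, Sncb at least 4.70-fold, Cryzl2 at least 4.66-fold and Crhr1 at least 4.49-fold higher, the brightest of them at 57.3. Zdhhc12 was 5.32-fold, the cytidine deaminase Apobec1 at least 4.80-fold, Hdhd3 at least 4.47-fold, Ulk3 at least 3.77-fold, Inhba at least 3.73-fold, Tnfrsf12a at least 3.58-fold, Oit3 3.54-fold, Tmem63b 3.51-fold and Zfp296 at least 3.39-fold lower, the brightest at 68.5 with the empty vector. Tnfrsf12a had a second probe set, which was lower too; the other 17 genes had none above the minimum.

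Treg-associated genes had 1 higher, 1 lower and 24 neither of 26 (median 0.01, -0.19 to 0.14, percentile 42.9). Itgae was 2.54-fold higher in the probe set used and at -0.25 in the second, and Nt5e (CD73) was at least 2.27-fold lower. Genes known as low in Treg cells had 0 higher, 3 lower and 9 neither of 12 (median 0.01, mean -0.29, percentile 49.5), the 3 being Il21, Igfbp4 and Il4. T cell cytokines had 1 higher, 3 lower and 8 neither of 12 (median -0.35, percentile 0.14, but -0.21 at percentile 6.44 with the minimum at the 75th percentile and -0.03 at percentile 2.64 without one), with Il24 2.22-fold lower and Il13 2.06-fold higher at a dim 32.1. Cell cycle genes had 0 past 2-fold of 24 and a median of -0.17 (-0.25 to -0.04) at percentile 0.01, with Bub1 at 1.37-fold and Mki67 at 1.27-fold lower. Cytokine receptors with STAT and SOCS genes had 0 of 25 (median -0.21, percentile 0.01, and -0.11 at percentile 1.19 with the minimum at the 75th percentile). Cholesterol synthesis had 0 of 13 (median -0.14, percentile 1.88, and 2.505 under quantile normalization) and interferon-stimulated genes 1 higher and 15 neither of 16 (median 0.21, percentile 99.6), the higher one being Mx1 at 2.23-fold. With the median of a gene's probe sets these medians were -0.06 at percentile 20.5 and 0.10 at percentile 91.2.

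Lists outside the extreme 2.5% at either end with the mutant and the settings used were helper lineage factors (0 of 13, median -0.14, but percentile 2.38 under quantile normalization and 0.94 with the median of a gene's probe sets), activation and checkpoint genes (0 of 18, median 0.01), naive and quiescence genes (0 of 12, median 0.11), chemokines and receptors (0 of 12, median 0.01, mean -0.02), T cell receptor signalling (0 of 15, median 0.06) and RUNX family and partners (0 of 7, median 0.03, mean -0.04). The others were glycolysis (0 of 13, median -0.03, mean 0.01), apoptosis (0 of 12, median 0.01, mean -0.03), heat shock (0 of 14, median -0.07) and the cytotoxic genes (1 lower and 10 neither of 11, median -0.12, percentile 4.91), where Gzma was the lower gene. B cell markers again lay low, with 3 lower and 4 neither of 7 (median -0.55, percentile 0.18), among them Fcer2a at 3.26-fold and Blnk at 2.19-fold. Myeloid markers had 2 higher and 5 neither of 7 (median 0.56, percentile 94.0, but 0.51 at percentile 98.2 with the median of a gene's probe sets), dendritic cell markers 1 higher and 5 neither of 6 (median 0.07, percentile 16.8), class II genes 0 of 5 (median -0.22, percentile 3.69) and CD8 T and NK cell markers 1 higher and 3 neither of 4 (median 0.01, percentile 46.3). The higher gene of both the myeloid and the NK list was Fcgr3 at 2.02-fold, with Csf1r at 2.41-fold and its second probe set at a log2 ratio of 0.77. The 1 stromal marker above the minimum, Sparc, was at least 2.06-fold higher, and no erythroid marker reached it. Second probe sets went the way of the call in 52 of 79 genes (65.8%, 54.3 to 76.1), and of 22 lists 1 lay in the highest 2.5% of random lists and 5 in the lowest 2.5%.

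Set directly against the mutant, wild-type Foxp3 gave higher signals of several Treg-associated genes and lower signals of Il4, Ctla2a and Bcl2, in a comparison that does not use the empty vector array. Cell cycle genes lay lower as a list, with none past 2-fold. Itgae was 5.82-fold higher, at 310.5 against 53.3, Il10 3.46-fold, Gpr83 2.79-fold and Ccr2 5.92-fold higher. Il4 was 7.81-fold lower, at 21.8 against 170.0, Ctla2a 9.47-fold lower and Bcl2 2.66-fold lower. Counts were 428 higher and 310 lower among 11271, and 84 higher and 53 lower among the 6766 bright genes.

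Further large differences between wild-type Foxp3 and the mutant were Enpep at least 21.3-fold, Postn at least 9.31-fold, Epcam 7.91-fold, the carboxypeptidase Cpm 7.40-fold, Stra6 at least 6.49-fold, the glutathione transferase Gstt1 6.47-fold, Ncmap at least 6.15-fold and Ermn 5.72-fold higher with wild-type Foxp3. Lower were Ctla2b at 6.09-fold, Lce3c at least 5.69-fold, Slc2a6 at least 4.97-fold, Dpf3 at least 4.91-fold, Obsl1 at least 4.73-fold, Epas1 at 4.70-fold, Vars2 at least 4.65-fold and Abcg3 at least 4.49-fold. Second probe sets of Epcam, Cpm, Itgae, Ermn, Epas1, Vars2 and Abcg3 had the same sign, with Epcam at 0.94 and Vars2 at -0.57 under 2-fold.

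Treg-associated genes had 5 higher, 1 lower and 20 neither of 26 (median 0.41, 0.22 to 0.70, percentile 100), Nt5e being at least 3.37-fold higher. Genes known as low in Treg cells had 0 higher, 4 lower and 8 neither of 12 (median -0.64, percentile 0, and -0.34 at percentile 0.01 without a brightness minimum), with Il21 3.34-fold, Igfbp4 2.27-fold and Pde3b 2.24-fold lower. Cell cycle genes had 0 past 2-fold of 24 and a median of -0.56 (-0.68 to -0.35) at percentile 0, with Birc5 at 1.92-fold and Ccna2 at 1.77-fold lower. Activation and checkpoint genes had 0 of 18 (median 0.21, percentile 99.9), with Egr1 at 1.80-fold higher, and cytokine receptors with STAT and SOCS genes 1 higher, 1 lower and 23 neither of 25 (median 0.18, percentile 99.8), with Il6st 2.13-fold higher and Il18rap 2.01-fold lower, the last with a second probe set at -0.46. Chemokines and receptors had 3 higher and 10 neither of 13 (median 0.36, percentile 98.6), Cxcr3 being 2.13-fold higher; with a brightness minimum at the 75th percentile this median was -0.01. B cell markers lay higher than with the mutant, with 2 higher and 5 neither of 7 (median 0.62, percentile 98.9, but percentile 95.6 with the median of a gene's probe sets), Fcer2a at 3.63-fold. Dendritic cell markers lay lower, with 3 lower and 3 neither of 6 (median -0.98, percentile 0.26, and -2.11 with the lower floor and -1.62 with no floor), Batf3 at least 2.15-fold.

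The remaining lists lay outside the extreme 2.5% at either end with the settings used. They were T cell cytokines (2 higher, 4 lower and 5 neither of 11, median -0.16), helper lineage factors (0 of 13, median 0.01), naive and quiescence genes (1 lower and 11 neither of 12, median -0.01, Klf2 at 3.21-fold), cytotoxic genes (1 higher, 2 lower and 7 neither of 10, median -0.01) and T cell receptor signalling (1 higher, Trat1 with a second probe set at -0.20, and 14 neither of 15, median -0.08). In the cytotoxic list the perforin gene Prf1 was 2.24-fold higher with a second probe set at -1.06, and Klrd1 was 2.59-fold and Fasl 2.08-fold lower. The others were the RUNX family (1 higher, Cbfa2t3 with a second probe set at 0.21, and 7 neither of 8, median -0.16, but -0.36 at percentile 0.56 with the minimum at the 75th percentile and -0.30 at percentile 0.735 without one), interferon-stimulated genes (1 higher, 1 lower and 16 neither of 18, median 0.10), glycolysis (0 of 13, median 0.11), cholesterol synthesis (0 of 13, median 0.06), apoptosis (1 lower and 11 neither of 12, median -0.09) and heat shock (0 of 14, median 0.13). Myeloid markers (2 higher and 7 neither of 9, median 0.41), class II genes (0 of 6, median -0.05, mean 0.09), CD8 T and NK cell markers (1 lower and 3 neither of 4, median -0.36) and stromal markers (0 of 2) lay there as well or had counts only, and no erythroid marker reached the minimum. With the median of a gene's probe sets the myeloid median was 0.90 at percentile 99.99 and that of CD8 T and NK cell markers -0.88 at percentile 0.16. Second probe sets went the way of the call in 139 of 174 genes (79.9%, 73.2 to 85.6), and 5 of 22 lists lay in the highest 2.5% of random lists and 3 in the lowest 2.5%.

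**Figure D2:**
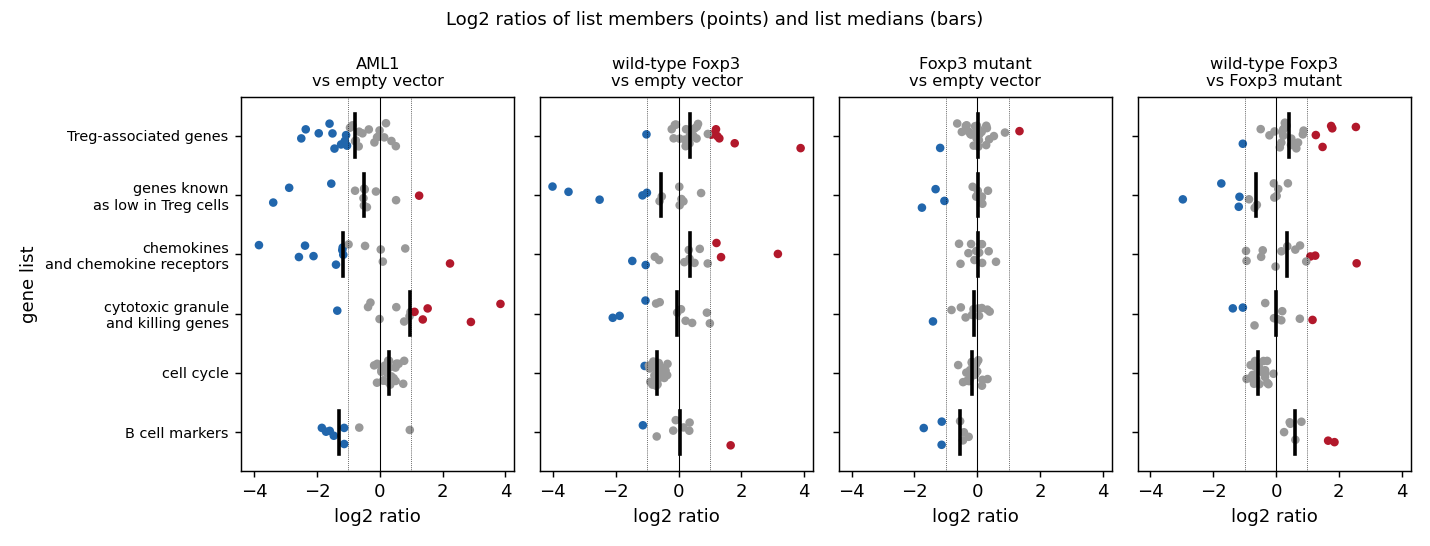
Log2 ratios of the members of 6 gene lists in the 4 comparisons, with 1 point per gene above the brightness minimum and a bar at the list median; red and blue points are genes higher or lower by 2-fold or more, and dotted lines mark log2 ratios of 1 and -1. The median of the Treg-associated genes is -0.77 with AML1, 0.37 with wild-type Foxp3 and 0.01 with the mutant, and that of cell cycle genes is 0.28, -0.68 and -0.17.

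The relation between the differences seen with wild-type Foxp3 and with the mutant was measured across genes with comparisons that share no array. AML1 then takes the place of the empty vector in a ratio, so its own differences enter with opposite sign. A negative relation between Foxp3 and AML1 differences would raise these values too. The log2 ratios of wild-type Foxp3 over the empty vector and of the mutant over AML1 had r = 0.13 (bootstrap interval 0.11 to 0.16, rho 0.16) across 10241 genes, and those of wild-type Foxp3 over AML1 and of the mutant over the empty vector had r = 0.18 (0.16 to 0.21, rho 0.19), where simulated unchanged arrays gave 0.00. Of 1492 genes called between wild-type Foxp3 and AML1 and off the floor in the other pair, 915 had the same sign in the mutant over the empty vector (61.3%, 58.8 to 63.8, simulated 50.4%). Of 852 called between wild-type Foxp3 and the empty vector, 507 had the same sign in the mutant over AML1 (59.5%, 56.1 to 62.8, simulated 49.8%). The difference between wild-type Foxp3 and the mutant was set against that between AML1 and the empty vector, which asks whether it runs against the AML1 pattern, and gave r = 0.02 (-0.00 to 0.05, rho -0.00). Its covariance of 0.0063 is by construction the difference between those of the pairs above, 0.0495 and 0.0433, so it is no separate measure. Of 633 genes called between wild-type Foxp3 and the mutant, 353 had the same sign in AML1 over the empty vector (55.8%, 51.8 to 59.7, simulated 50.4%), and of 934 called with AML1, 465 had the same sign in wild-type Foxp3 over the mutant (49.8%, 46.5 to 53.0, simulated 50.2%).

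Against the shared empty vector, 122 genes were higher with both wild-type Foxp3 and the mutant, where 8.76 are expected of independent lists and 30.7 in simulations without effects, and 47 were lower with both, where the values are 3.66 and 48.6. Most of these genes were dim: 14 of the higher and 9 of the lower genes were bright. The bright genes included Mpzl2, Itgae and Rgs2 on the higher side and Il21, Gzma, Epas1, Igfbp4 and Il4 on the lower side. The simulated arrays had equal means for every gene, so they hold no shift of dim signals between arrays. On the empty vector array 42.5% of probe sets lay at or below the floor. The values were 38.1% with wild-type Foxp3 and 38.5% with the mutant. Whether such a shift gave the excess of shared higher genes was not tested, here or in the pairs below. The correlation of wild-type Foxp3 and the mutant, each over the empty vector, was 0.53 against a simulated 0.50. It was 0.495 under quantile normalization, 0.481 without a brightness minimum and 0.572 with the minimum at the 75th percentile. The covariance was 0.107 against a simulated 0.0703, and part of the excess may come from the shared control, a single array that cannot be split. Il4, Il21, Igfbp4 and Epas1 had their highest signal of all 4 arrays on the empty vector array. Wild-type Foxp3 and AML1 had 66 genes lower in common (12.04 independent, 47.5 simulated), among them Il21, Il4, Myo6, Igfbp4, Cxcr4, Epas1 and Klf2, and 103 higher in common (14.5 and 31.5). A further 22 genes were higher with wild-type Foxp3 and lower with AML1 (16.4 and 0.2), among them Itgae, Il10, Cxcr3, Izumo1r and Gpr83, and 10 were lower with wild-type Foxp3 and higher with AML1 (10.7 and 0.2), among them Gzma and Aqp9. The simulated 0.2 is low by construction, since no gene was changed and a shared array pushes both ratios the same way. Of these genes, 14 of the 22 and 8 of the 10 were bright. The counts of 22 and 10 lay near the independent values, but the shared array lowers such counts. They therefore neither show nor exclude opposition between the 2 factors. The correlation of these 2 comparisons was 0.21 against a simulated 0.50, and the covariance 0.0637 against 0.0703. For the mutant and AML1 it was 0.26 against 0.50, with covariances of 0.0574 and 0.0701. With the brightness minimum at the 75th percentile these correlations were 0.137 and 0.167. Changes particular to either array lower a correlation below the simulated 0.50, so these values do not by themselves show opposed changes. The mutant and AML1 shared 67 higher genes (6.08 and 31.6), of which 1 was bright, and 49 lower genes (5.92 and 48.4), of which 7 were bright.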

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

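The tests of the 3 patterns weighed here, and their limits, were chosen after the values had been seen, although quantile normalization and median centring were planned as alternatives. The limits of the single probe set test and of the test on Runx3 were revised once more after their first outcomes were seen, and the test of scatter for the mutant was replaced by one on arrays it does not share. A test of the same scatter on bright genes called with wild-type Foxp3 was dropped as void, because genes chosen as bright leave out dim scatter by construction. Control probe sets for poly-A RNA added before labelling, which enter no comparison, were brighter on the other arrays than on the empty vector array. After scaling, their median fold over the empty vector was 1.363 for AML1, 1.508 for wild-type Foxp3 and 1.258 for the mutant, with 24 of 24 probe sets higher on each. Control probe sets for RNA added at hybridization had median folds between 1.03 and 1.07, with 14, 13 and 10 of 18 higher. As deposited, before scaling, the median log2 ratios were 0.36, 0.36 and 0.14 for the poly-A controls. Those of the hybridization controls were 0.01, -0.17 and -0.14, in the same order. Among bright probe sets without a single named gene, 21 were at least 2-fold higher with AML1, 21 with wild-type Foxp3 and 3 with the mutant than with the empty vector, and 63, 28 and 9 were lower.

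Runx1 gave a lower signal on the array labelled AML1 than on the empty vector array. Noise of a single probe set is argued against by values already part of the pattern and not by a separate test, since 5 of the 5 other probe sets were lowest on that array too. An exchange of the AML1 and empty vector arrays, if Foxp3 leaves Runx1 alone, is argued against as well, again by the same 6 probe sets and not by a separate test: the Foxp3 arrays lay nearer to the array labelled empty vector, with a median difference of log2 distances of 1.188 and 11 of 12 values above 0. Lower RNA of the cells' own Runx1 and Runx3 when AML1 is supplied from the vector is a candidate explanation that cannot be told apart from a wrong label or a swap with an outside sample, because no probe set is known to lie inside the insert. Runx3 was lower in both probe sets, with the smaller log2 ratio at -1.554, and the highest Runx1 log2 ratio was -0.70.

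Genes called with the mutant were mostly dim and mostly higher. Scatter of dim probe sets may account for part of them, since second probe sets went the way of the call in 64.4% of 59 dim genes (exact interval 50.9 to 76.4) and 0.53% of bright genes were called, although the share was a similar 70% of 20 bright genes (45.7 to 88.1), so it does not set dim genes apart. As the whole cause it is argued against for the dim higher genes, of which 62.8% of 293 were also higher in wild-type Foxp3 over AML1, which shares no array (57.0 to 68.3), against 50.8% of dim genes not called, and 59.5% against 48.2% under quantile normalization; for the dim lower genes it stays open, with 55% of 111 also lower (45.2 to 64.4) against 49.2%. Scaling between arrays as the source of the excess of higher genes stays open. Under quantile normalization 60.3% of calls were higher, against 72.4% with the scaling used, which lies between the limits set for either outcome. Median centring left 72.8%, but as a single factor per array set on the brighter probe sets it cannot undo a shift of dim signals alone. With the scaling used, 42.5% of probe sets lay at or below the floor on the empty vector array and 38.5% on the mutant array. The median log2 ratio of the mutant over the empty vector was 0.10 for dim genes and -0.005 for bright genes. Whether Foxp3 or a technical property of both Foxp3 arrays gave the shared part was not tested.

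B cell genes gave lower signals on the array labelled AML1. A smaller carry-over of B cells from the splenocytes that presented antigen is consistent with 7 of 7 further B cell genes lying below 0 (median log2 ratio -1.19, from -0.70 for Ly86 to -1.69 for Cd22), although these values had been computed before the test was set, and Cd37 and Pou2af1 are also expressed by activated T cells. Ighm read 386.4 against 1166. Of 17 B cell and class II genes only 1 lay above 0, H2-Ab1 at 0.35, which B cells also express strongly and which ran against this explanation. Pax5, a preset B cell marker left out of the 17, also ran against it, at a dim 17.3 against 2.3 with the empty vector. Cr2, left out as well, went with this explanation at 8.6 against 19.6. The lower value of each lay below the floor. H2-Aa at -1.50, Cd74 at -1.34 and H2-Eb1 at -0.68 went with it. The sort for infected cells would remove uninfected B cells. The 17 genes also lay low with the mutant over the empty vector (median -0.43, percentile 0, 3 above 0), but not with wild-type Foxp3 (median -0.06, percentile 17.4, 7 above 0). The pattern is therefore not confined to the AML1-labelled array. Scaling between arrays is argued against, since random lists matched on signal had a median of 0.13 in this comparison. Quantile normalization and median centring left the weaker list median at -1.31. They add little, because they moved the median of all genes only from 0.058 to 0.054 and 0.039. A direct effect of AML1 on these genes was not tested.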

How the results depend on the processing

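The split into dim and bright genes was chosen after the data were seen; the other alternatives were planned. Of 2035 log2 ratios of named genes over the 5 alternatives that can change one, 1866 stayed within 1.5-fold and on the same side of the 2-fold rule and 169 did not; 19 turned sign, 0 of them called ratios. The higher brightness minimum, its removal and the rule on the sign of all probe sets leave these ratios as they are by construction. Of 600 list medians over the 7 alternatives that can change one, 33 turned sign. Of these, 1 was the median of a list in the extreme 2.5% of random lists. The interval of the list's members was left by 2 medians, both for dendritic cell markers in wild-type Foxp3 against the mutant. They lay at -2.11 with the lower floor and -1.62 with no floor. That interval is wide and spans all members of a short list, so staying inside it does not show that a median held still. T cell cytokines with wild-type Foxp3 stayed inside it at 0 without a brightness minimum, against -0.49 with the settings used. Counts of higher genes stayed within 1.5 times in 26 cases and moved in 6, and counts of lower genes stayed in 28 and moved in 4. With the brightness minimum at the 75th percentile, which tests fewer genes by construction, 172 genes were higher and 199 lower with AML1, 132 and 112 with wild-type Foxp3, 21 and 14 with the mutant, and 84 and 53 in wild-type Foxp3 against the mutant. Of the 20 named genes with the largest differences, 2 were then still called for the mutant against the empty vector and 11 for wild-type Foxp3 against the mutant. The same minimum moved the correlation of wild-type Foxp3 over AML1 with the mutant over the empty vector to 0.264 and the share of genes with the same sign to 66.5%, and turned the median of chemokines and their receptors in wild-type Foxp3 against the mutant to -0.014; the cause was not tested. With no brightness minimum the correlation was 0.154, while no call changed, because a call already needs a signal above that minimum. The count of higher genes with the mutant was 547 with the floor at the 20th percentile and 223 with the median of a gene's probe sets. A lower floor can only add calls by construction, since it widens ratios whose dimmer signal lay below the floor used. It kept all 497 calls with the mutant and gave 746. The cause of the smaller count with the median of probe sets was not tested. The median of probe sets kept the calls and directions of 64.3% of genes called with AML1, 60.6% with wild-type Foxp3, 52.5% with the mutant and 58.5% in wild-type Foxp3 against the mutant, where 1 call turned, and quantile normalization kept 93.5%, 83.6%, 84.1% and 91.7%.

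The Treg-associated list kept its place among the extreme 2.5% of random lists in 8 of 8 settings that can change a median, the one used included, for AML1 (medians -0.79 to -0.67), wild-type Foxp3 (0.29 to 0.47) and wild-type Foxp3 against the mutant (0.29 to 0.48), and the cell cycle list did so in 8 of 8 in all 4 comparisons. Other lists lost theirs under some settings. With the mutant, T cell cytokines and cholesterol synthesis kept it in 6 of 8 settings and interferon-stimulated genes in 7 of 8. With wild-type Foxp3, T cell cytokines kept it in 7 of 8 and myeloid markers in 6 of 7. With AML1, CD8 T and NK cell markers kept it in 6 of 7 and apoptosis genes in 7 of 8. In wild-type Foxp3 against the mutant, B cell markers kept it in 6 of 7 and chemokines with their receptors in 7 of 8. In all, 11 such places were lost among 225 and 13 gained among 375, and 16 of the 225 medians moved by over 1.5 times; 6 gains came with the median of probe sets, 3 without the brightness minimum, 2 with the higher one, 1 with quantile normalization and 1 with median centring. No paired analysis was possible because each group has 1 array and no result comes from a test. Signals near the floor of 8.95 limit the dim genes, where folds are bounds or scatter widely.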

Other observations

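The tests in this part were chosen after the values had been seen, as were its gene groups, and the limit of the immediate early gene test was revised after its first outcome was seen. Metallothioneins, which bind zinc and copper, had higher signals on the array labelled wild-type Foxp3: Mt1 had a log2 ratio of 1.71, Mt2 of 2.75 and Mt3 of 1.58 over the empty vector, and 1.56, 2.29 and 2.43 over the mutant. With the mutant their median over the empty vector was 0.15, and with AML1 it was 0.30. Mt3 lay at -0.84 with the mutant, beside 0.15 for Mt1 and 0.46 for Mt2, so its value over the mutant also holds that low signal. A test on these genes was run and dropped as void, because they had been picked for this pattern.

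Of 18 immediate early genes, which respond quickly to stimulation, 4 were higher by 2-fold or more with wild-type Foxp3 than with the empty vector, namely Fos at 2.08, Nr4a2 at 1.21, Jun at 1.38 and Egr1 at 1.11 on the log2 scale, and 0 were lower. Against the mutant 3 were higher, with Fos at 2.40, Jun at 1.56, its second probe set at 0.67, and Nr4a2 at 1.23. A higher signal of the whole group may lie behind this, but the list stood at percentile 95.4 and 93.9 of matched random lists in the 2 comparisons, which decides neither way. With the mutant over the empty vector 5 of the 18 genes lay above 0, with a median of -0.17 at percentile 0.19, so the comparison with the mutant also holds its low values. Ier3 and Egr2 lay at -0.70 and -0.52 with wild-type Foxp3 over the empty vector.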
